A study of Homo sapiens with 6 samples.

How the data were processed

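Bulk RNA sequencing was performed on AC16 cells, an established human cardiomyocyte line, with 3 libraries from vehicle-treated cells (control) and 3 from cells given 6.25 µM of the zinc chelator TPEN for 24 h. Per the labels' protocols, RNA was taken up in TRIzol, enriched for poly(A) and sequenced on a BGISEQ instrument. The deposited table holds estimated counts per gene (expected counts), made by the authors and not scaled to a common total, with the mean of each group beside them. The genome build GRCh38 and the tool DESeq2 are named in the submitters' processing notes. The aligner, the counting tool and the use of strand in counting are not given in the sources used here. Of 78932 genes, 36187 had no symbol and 43672 were at 0 in all 6 libraries. Of the values above 0, 70.3% to 71.7% were whole numbers. Library totals ran from 20045117 to 22765766 counts.

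Counts were rounded to whole numbers, filtered with edgeR's filterByExpr by group and scaled by the TMM method, which left 16010 genes (12806 protein-coding, 2568 long non-coding and 636 others). The groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and a biological coefficient of variation of 8.07%. Large changes were those of at least 2-fold. Log2 changes are TPEN minus control, given with the standard error, and CPM values are means with the SD of 3 libraries. The standard error was worked back from the unshrunken coefficient and the F statistic of the test, so it is approximate. A gene at 0 in a whole group was compared with a floor of 3 counts over the group, which covers counting error only. Shares of counts were compared by an exact two-sided permutation test, whose smallest p with 3 against 3 libraries is 0.1.

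The test, the filter, 42 gene lists and the rule for naming genes were chosen before the data were examined. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and then with an estimated correlation, and with fry, which asks only whether the genes of a list move one way on balance, each adjusted over the lists. Counts of rising and falling members were also adjusted over the list alone. The list of zinc finger genes was taken by the symbol ZNF followed by a number, so not every member need carry a KRAB domain. Genes could be named by this rule: the 12 with the largest rise and the 12 with the largest fall among called genes with a mean of at least 1 CPM, a plain symbol and groups that do not overlap, every measured metallothionein, ZIP and ZnT gene, up to 4 called members of each other list with the largest change, and MTF1, TNNT2, ACTC1, GAPDH and ACTB. GO and KEGG terms carried by the deposited table were tested by a one-sided Fisher's exact test of genes that changed at least 2-fold, against tested genes with any such term, for terms of 10 to 500 genes (2729 GO and 324 KEGG), adjusted over terms and directions. Coordinates, exon numbers and overlaps came from GENCODE release 29 on GRCh38, matched by gene identifier.

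The alternatives were RLE, upper-quartile or library size scaling, no low count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom, the replicate number as a block, and leaving out each library in turn. For terms they were no fold minimum and all tested genes as background. Restricting the test to protein-coding genes or to genes with 2 or more exons was added after the data were seen. The procedure was tested on simulated data of the same size, where edgeR recovered 61.8% of genes changed 1.5-fold, 81.8% of those changed 2-fold and 95.5% of those changed 4-fold, with 6.47% of calls false. A simulated list was found by all 3 set tests with 0 other lists called. In the gene simulation only 68, 66 and 66 of 16010 genes were changed 1.5-fold, 2-fold and 4-fold, in either direction. Genes were drawn independently of each other in both simulations. They therefore do not show how the scaling fares when most genes change, or how the set tests fare when genes are correlated. Random gene sets called 0 GO and 0 KEGG terms, and a simulated term ranked 1, with 112 other terms also called. No library was left out, and Reactome pathways in the table were not tested.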

Results

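RNA from AC16 cells was measured by bulk sequencing after 24 h with the chelator TPEN or with vehicle. AC16 is an established human cell line with cardiomyocyte features, made by fusing ventricular heart cells with transformed fibroblasts. TPEN is a cell-permeable molecule that binds zinc tightly and can also bind iron and copper. The series held 6 libraries, 3 from vehicle-treated cells (control) and 3 from cells treated with 6.25 µM TPEN, and the series' design text calls the libraries of each group independent biological replicates. The deposited table gave an estimated read count for each of 78932 genes in each library. Total counts were 21605846, 20338781 and 22765766 in control replicates 1, 2 and 3, and 20757732, 20045117 and 20899466 in TPEN replicates 1, 2 and 3. Counts above 0 were recorded for 24419 ± 312 genes in control and 26887 ± 478 in TPEN (SD, n = 3), with no overlap between the groups and an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give.

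The design holds a single comparison, TPEN against control, which asks how RNA levels in these cells differ after the chelator. Zinc levels are not part of the data used here. TPEN changed most of the measured transcriptome. Most measured members of the heat shock, immediate early, NF-kB and hypoxia lists rose, and most of the DNA replication and ZNF-numbered zinc finger lists fell. Of these list calls, that of the NF-kB list alone held with an estimated correlation. That setting also weakened lists whose estimated correlation was below the preset value, so a lost call does not by itself show correlated genes. Of 16010 genes with enough counts to test, 4985 rose and 4821 fell at an adjusted p below 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At least 2-fold changes were found for 1864 rising and 1166 falling genes. Protein-coding genes divided nearly evenly among these, with 987 rising and 951 falling, whereas long non-coding RNA genes leaned upward, with 752 rising and 163 falling. Fitted alone, protein-coding genes gave 1057 rising and 875 falling. The balance of all called genes depended on the scaling, with 4794 rising and 5055 falling by library size alone and 5317 and 4444 by upper-quartile scaling. Among at least 2-fold changes, rises outnumbered falls under both (1825 and 1211, 1956 and 1092).

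The 6 libraries separated by treatment along the first principal component, which held 90.7% of the variance. TPEN replicate 1 stood apart from the other TPEN libraries. Its counts differed from those of TPEN replicates 2 and 3 by a chi-square per degree of freedom of 16.6 and 19.6, against 2.67 to 4.68 for the remaining pairs within a group. Without TPEN replicate 1, 11153 genes passed the test and 3465 of them changed at least 2-fold. The groups did not overlap for 10635 of the tested genes, where chance alone gives 10%. The same held for every gene named below as rising or falling with all 6 libraries, except ADAM8. For the largest rises and falls this was a condition of being named, and the others had passed the test on the same libraries. It is therefore not separate support for the named genes.

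Genes that handle zinc did not move in a single direction. SLC39A10, a ZIP transporter that carries zinc into the cytosol, rose from 44.3 ± 2.55 to 124 ± 7.42 counts per 1000000 (CPM, SD, n = 3), a log2 change of 1.48 ± 0.07 (SE, edgeR adjusted p = 3.99e-08). SLC39A9, SLC39A14, SLC39A6 and SLC39A7 rose by 0.63, 0.48, 0.40 and 0.26 on the log2 scale. In all, 5 of 10 measured ZIP genes rose and none fell, 5 and 0 when adjusted over the list alone, although the list as a set missed the threshold (camera adjusted p = 0.0702, and adjusted p = 0.348 with an estimated correlation). Without a low count filter it was called, with 14 genes and a median of 0.39 (camera adjusted p = 0.041). Without TPEN replicate 1, SLC39A8 also rose (0.46) and SLC39A1, SLC39A3 and SLC39A13 fell by 0.18, 0.25 and 0.27. With all 6 libraries these 4 genes stood at 0.34, -0.11, -0.13 and -0.15, and SLC39A11 at 0.28. SLC39A8 was also called with upper-quartile scaling, a filter of 1 CPM in 3 libraries and the replicate block (edgeR adjusted p = 0.0376, 0.0427 and 0.0283), and SLC39A11 with upper-quartile scaling and without control replicate 2 (0.043 and 0.0353). Among 7 measured ZnT genes, most of whose products move zinc out of the cytosol, SLC30A7 rose by 0.73 while SLC30A4 (log2 change -0.82) and SLC30A3 (-0.94) fell, and 1 rose and 1 fell when adjusted over the list alone. SLC30A5, SLC30A6 and SLC30A9 stood at 0.02, -0.15 and 0.11 and did not pass the test, and SLC30A5 was -0.028 without a low count filter, while SLC30A9 was called without TPEN replicate 1 (0.17). SLC30A3 was near the detection limit at 0.697 ± 0.136 CPM in control, and its call was lost whenever any single library other than TPEN replicate 2 was left out, and also with RLE or upper-quartile scaling and without a low count filter (edgeR adjusted p = 0.0513, 0.0586 and 0.062). The plasma membrane exporter SLC30A1 had 37.2 ± 0.687 CPM in control and 33.6 ± 3.99 in TPEN (log2 change -0.15 ± 0.09, edgeR adjusted p = 0.176), and passed the threshold without TPEN replicate 3 (-0.24, edgeR adjusted p = 0.0440, against a range of 0.0440 to 0.406 over its alternatives). The ZnT list as a set was not called (median -0.15, from -0.18 without TPEN replicate 3 to -0.068 without TPEN replicate 1, camera adjusted p = 0.914).

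Metallothionein genes, whose transcription follows cellular zinc through the factor MTF1, did not fall as a group. MT2A, the most abundant of them here, rose from 128 ± 10.7 to 170 ± 24.2 CPM (SD, n = 3), a log2 change of 0.41 ± 0.10 (SE, edgeR adjusted p = 0.00489). MT1E had a log2 change of 0.12 ± 0.14, MT1X of -0.16 ± 0.14 and MT1F of 0.56 ± 0.38, and none of these 3 passed the test (edgeR adjusted p = 0.502, 0.324 and 0.218). The list had 4 measured members, of which 1 rose, also when adjusted over the list alone, and its median log2 change of 0.26 was not called (camera adjusted p = 0.897). TPEN replicate 1 had the lowest value of the TPEN libraries for MT2A, MT1E and MT1X, and without it MT1E was also called (log2 change 0.27, edgeR adjusted p = 0.0237, against a range of 0.0237 to 0.696 over its alternatives). Without TPEN replicate 2 the list median was -0.01 and MT1E stood at -0.07, so the direction of the list rested on single libraries. Over all alternatives the list median ran from -0.01 to 0.40. These genes lie in a cluster on chromosome 16 and resemble each other closely, so the division of reads among them is uncertain. MTF1 itself rose by 0.57 ± 0.08 (SE, edgeR adjusted p = 6.58e-05), from 36.6 ± 1.74 to 54.2 ± 2.84 CPM.

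**Figure D1:**
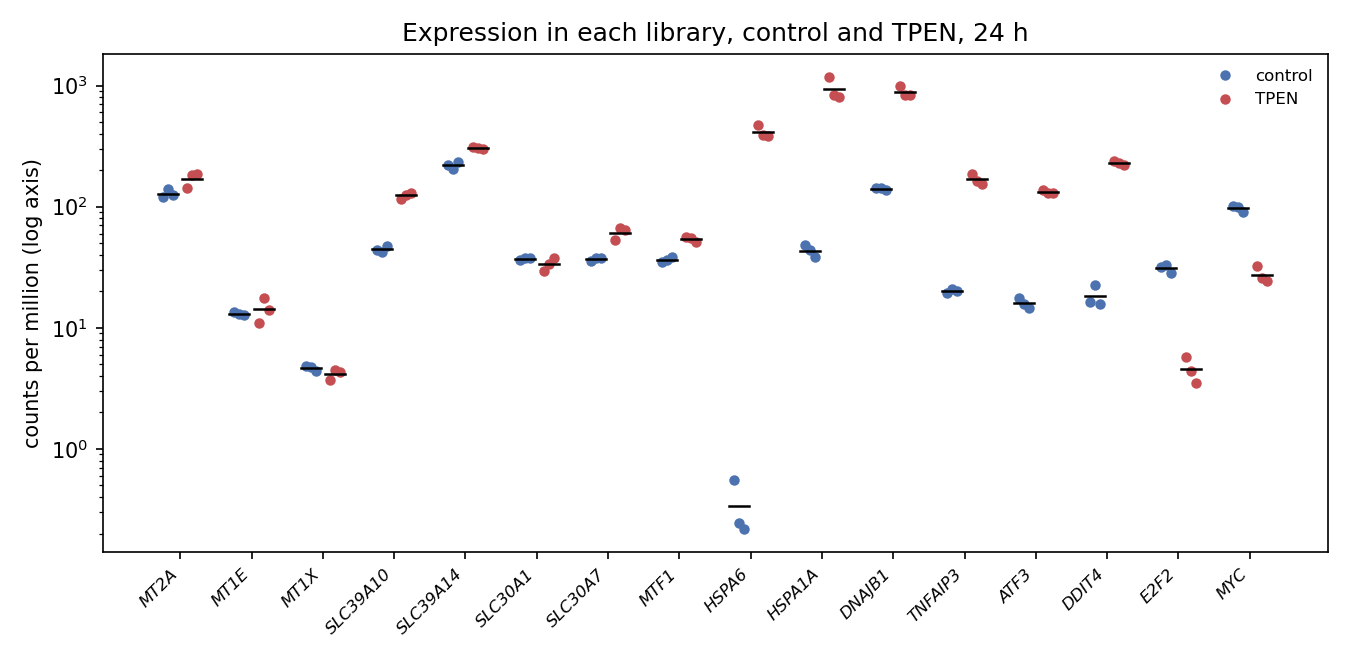
Counts per 1000000 (CPM) in each library on a log axis, with blue points for control, red points for TPEN and a black bar at the mean of the 3 libraries. SLC39A10 rose from a mean of 44.3 to 124, MT1X had means of 4.65 and 4.15, and HSPA6 went from 0.339 to 415.

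The largest log2 rise among the named genes was that of HSPA6. This inducible Hsp70 chaperone gene with a single exon on chromosome 1 (positions 161524540 to 161526910, GRCh38) went from 0.339 ± 0.187 to 415 ± 51.1 CPM (SD, n = 3), a log2 change of 10.24 ± 0.19 (SE, edgeR adjusted p = 1.23e-10). The inducible Hsp70 genes HSPA1A and HSPA1B rose by 4.44 and 4.89, and DNAJB1, an Hsp40 partner, by 2.65. HSPA1A and HSPA1B are nearly identical copies, so the share of reads given to each is uncertain. Of 20 measured heat shock genes 16 rose and 1 fell, 16 and 1 when adjusted over the list alone, with a median log2 change of 0.81 (camera adjusted p = 1.84e-17, and adjusted p = 0.0743 with an estimated correlation).

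Several early response transcription factors were raised at 24 h. EGR3 rose by 6.12 ± 0.24, NR4A3 by 5.73 ± 0.16, and FOSB by 5.28 ± 0.19 (log2, SE, n = 3 per group), and NR4A1 from 9.45 to 151 CPM. The immediate early list had 28 measured genes, of which 18 rose and 4 fell, 18 and 4 when adjusted over the list alone, with a median of 1.36 (camera adjusted p = 1.65e-13, and adjusted p = 0.348 with an estimated correlation). Inflammatory genes driven by NF-kB rose with them. IL1A, an alarm cytokine, rose by 6.55 ± 0.35 from 0.0626 to 6.32 CPM, PTGS2, the inducible cyclooxygenase, by 4.64, TRAF1 by 3.12 and TNFAIP3, a feedback inhibitor of NF-kB, by 3.06. The control counts of IL1A were 3, 1 and 0 and those of PTGS2 7, 1 and 2, so their sizes rested on few counts. Without control replicate 1 the log2 changes were 7.76 and 5.73, and without control replicate 3 that of IL1A was 5.96. Of 22 measured NF-kB genes 18 rose and 1 fell, 18 and 1 when adjusted over the list alone, with a median of 1.17 (camera adjusted p = 2.85e-15). This was the only list whose call held with an estimated correlation, at adjusted p = 0.0331 with an estimated correlation. Interferon-stimulated genes went both ways, with 6 rising and 6 falling of 22, the same numbers when adjusted over the list alone. Among them IFIH1 rose by 1.04 and STAT2 and IRF9 fell by 0.96 and 1.00 on the log2 scale, and the set was not called (median -0.04, from -0.096 without control replicate 1 to 0.023 without control replicate 3, mean 0.03, a test pointing down, camera adjusted p = 0.957).

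Hypoxia targets of HIF1 rose almost throughout. Of 27 measured members 23 rose and none fell, 24 and 0 when adjusted over the list alone, with a median log2 change of 0.81 (camera adjusted p = 3.63e-13, and adjusted p = 0.141 with an estimated correlation). ANGPTL4, a secreted lipase inhibitor, rose by 4.73 ± 0.23, ANKRD37 by 2.47, the hexokinase gene HK2 by 2.38 and INSIG2 by 2.34. The wider glycolysis list had 6 rising genes and 1 falling gene of 19, 6 and 0 when adjusted over the list alone, among them ENO2 (0.72), SLC16A1 (0.59) and LDHA (0.45). As a set it missed the threshold (median 0.13, from 0.076 without control replicate 3 to 0.17 without TPEN replicate 3, camera adjusted p = 0.0653). It passed when control replicate 2, TPEN replicate 1 or TPEN replicate 3 was left out (camera adjusted p = 0.0358, 0.0376 and 0.0265). With upper-quartile scaling and without a low count filter it also passed (camera adjusted p = 0.048 and 0.0366). The camera adjusted p was 0.752 with an estimated correlation, and the fry adjusted p was 0.0157.

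Metal genes beyond zinc moved in both directions. The transferrin receptor gene TFRC rose from 227 ± 9.19 to 499 ± 16.7 CPM (log2 change 1.14 ± 0.06), the mitochondrial iron importer SLC25A37 by 0.93 and the heme oxygenase gene HMOX1 by 1.49. SLC40A1, which encodes the iron exporter ferroportin, went from 3.82 ± 0.354 to 0.524 ± 0.0876 CPM, a log2 change of -2.86 ± 0.22 (SE, edgeR adjusted p = 9.17e-07). Of 17 iron genes 8 rose and 7 fell, 8 and 8 when adjusted over the list alone, and the set was not called (median 0.08, from -0.014 without TPEN replicate 1 to 0.15 without TPEN replicate 2, camera adjusted p = 0.66). For copper, the transporter ATP7A rose by 0.97 and the chaperone COX17 by 0.71, while SCO2 (-1.36) and SLC31A2 (-0.90) fell. In total 6 of 13 copper genes rose and 2 fell, 7 and 2 when adjusted over the list alone (median 0.24, camera adjusted p = 0.372).

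Among the ATF4 targets and the genes of endoplasmic reticulum stress, rises outnumbered falls. DDIT4, an inhibitor of mTORC1 signalling, rose by 3.67 ± 0.12, ATF3 by 3.05 ± 0.08, CHAC1, a glutathione-degrading enzyme, by 2.46 ± 0.19 and PPP1R15A by 2.09 ± 0.09. Of 31 ATF4 targets 17 rose and 4 fell, 17 and 4 when adjusted over the list alone, with a median of 0.39 (camera adjusted p = 2.83e-05, and adjusted p = 0.494 with an estimated correlation). Among 23 chaperone and degradation genes of the endoplasmic reticulum 17 rose and 1 fell, 17 and 1 when adjusted over the list alone, with a median of 0.28 (camera adjusted p = 0.00465, and adjusted p = 0.141 with an estimated correlation). HERPUD1 rose by 1.45, DNAJB9 by 1.35 and XBP1 by 1.12, and the ubiquitin ligase gene SYVN1 fell by 0.65. NRF2 targets gave 12 rises and 4 falls of 27, the same when adjusted over the list alone, led by ABCC2 (2.76) and OSGIN1 (1.60), and were not called as a set (median 0.15, from 0.098 without TPEN replicate 2 to 0.17 without control replicate 1, camera adjusted p = 0.237). Antioxidant enzymes, including SOD2 (0.81), PRDX4 (0.62), GPX8 (0.55) and PRDX1 (0.46), had 8 rises and 2 falls of 19, the same when adjusted over the list alone (median 0.13, camera adjusted p = 0.237).

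Genes tied to cell death changed without a common direction, apart from the ferroptosis list. Of 20 measured ferroptosis genes 13 rose and 3 fell, 13 and 3 when adjusted over the list alone, with a median of 0.24 (camera adjusted p = 0.00268, and adjusted p = 0.141 with an estimated correlation). Its leading members, PTGS2, CHAC1, HMOX1 and the cystine transporter gene SLC7A11 (18.0 CPM in control, 44.4 in TPEN), are also held by the inflammatory, ATF4 or NRF2 lists. Of 34 apoptosis regulators 13 rose and 15 fell, 13 and 16 when adjusted over the list alone. PMAIP1, which encodes the pro-death protein NOXA, rose by 2.25, the inhibitors of apoptosis BIRC3 and BIRC2 by 2.19 and 1.73, and the initiator caspase gene CASP9 by 1.57. The median of that list was -0.11, from -0.15 without TPEN replicate 2 to -0.068 without TPEN replicate 1, whereas its mean was 0.09 and the test pointed up (camera adjusted p = 0.372). In the pyroptosis and necroptosis list, NLRP3 (2.72), MLKL (1.33) and IL1B (1.13) rose and RIPK1 fell from 59.4 ± 0.17 to 16.1 ± 1.19 CPM, a log2 change of -1.88. It had 5 rises and 4 falls of 12, the same when adjusted over the list alone, with a median of -0.13, from -0.17 without control replicate 3 to -0.054 without TPEN replicate 2, a mean of 0.27 and a test pointing up (camera adjusted p = 0.914). Targets of p53 included GADD45A (2.36) and FAS (1.08), with 13 rises and 6 falls of 29, the same when adjusted over the list alone (median 0.23, from 0.090 without control replicate 3 to 0.27 without control replicate 2, camera adjusted p = 0.093). Without TPEN replicate 1 the p53 list was called (median 0.19, camera adjusted p = 0.0376). With all 6 libraries its camera adjusted p was 0.439 with an estimated correlation, and its fry adjusted p was 0.00074.

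In the lists for DNA replication, mitosis and DNA repair, falls outnumbered rises. E2F2, a transcription factor of S phase entry, went from 31.3 ± 2.47 to 4.54 ± 1.15 CPM, a log2 change of -2.78 ± 0.15, and GINS3, a part of the replicative helicase, had a change of -2.19 ± 0.09. The cyclin E genes CCNE1 and CCNE2 fell by 1.96 and 1.77 on the log2 scale. Of 41 DNA replication genes 29 fell and 1 rose, 29 and 1 when adjusted over the list alone, with a median of -0.28 (camera adjusted p = 2.12e-05, and adjusted p = 0.141 with an estimated correlation). Of 33 mitosis genes 21 fell and 3 rose, 21 and 3 when adjusted over the list alone, among them PLK1 (-1.20), KIF11 (-0.89), BUB1B (-0.70) and NEK2 (-0.63). That list's median was -0.23 (camera adjusted p = 0.0329, and adjusted p = 0.496 with an estimated correlation), and its call was lost without control replicate 3 (camera adjusted p = 0.0572, with a range of 7.84e-05 to 0.496 over its alternatives) and with a filter of 1 CPM in 3 libraries (0.065). Of 29 DNA repair genes 17 fell and 4 rose, 18 and 4 when adjusted over the list alone, with a median of -0.28 (camera adjusted p = 0.00854, and adjusted p = 0.494 with an estimated correlation). Its members BARD1, PALB2, EXO1 and RAD54L fell by 1.16, 1.13, 1.09 and 0.93. MYC fell from 96.6 ± 5.92 to 27.4 ± 4.41 CPM, a log2 change of -1.82 ± 0.11. Of 17 measured replication-dependent histone genes, most of them near the detection limit in these poly(A) libraries, 3 fell and 1 rose, 0 and 0 when adjusted over the list alone (median -0.10, from -0.27 without control replicate 2 to -0.085 without control replicate 3, camera adjusted p = 0.914).

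Zinc finger genes and single-exon genes were among the deepest falls. The list of genes whose symbol is ZNF and a number had 460 measured members, of which 237 fell and 93 rose, 237 and 94 when adjusted over the list alone, with a median of -0.45 (camera adjusted p = 1.31e-05, and adjusted p = 0.143 with an estimated correlation). ZNF786 went from 3.89 ± 0.711 to 0.0823 ± 0.0584 CPM, a log2 change of -5.47 ± 0.38, or -6.16 without TPEN replicate 2. ZNF606, ZNF619 and ZNF746 changed by -4.01, -3.94 and -3.89. Among other strongly falling genes, HPS6, a subunit of a complex for lysosome-related organelles encoded by a single exon on chromosome 10 (positions 102065390 to 102068038, GRCh38), went from 41.5 ± 2.56 to 0.654 ± 0.0409 CPM, a log2 change of -5.98 ± 0.13 (SE, edgeR adjusted p = 2.43e-10). PLAGL2, a zinc finger transcription factor on chromosome 20 (positions 32192503 to 32207791), went from 103 ± 1.94 to 2.54 ± 0.478 CPM, a log2 change of -5.34 ± 0.11. USP27X, TMEM177, EXO5 and ZBTB39 changed by -5.03, -4.73, -4.58 and -4.45, and RIOX1, PPP1R3D and DDX28 by -4.43, -4.37 and -4.01. USP27X had 1, 4 and 0 counts in the TPEN libraries, and its fitted change without TPEN replicate 2 was -6.58. RIOX1, PPP1R3D and DDX28 each overlap another protein-coding gene on the opposite strand, and the sources used here do not say whether counting used strand, so their values are uncertain. RSC1A1 had 0 counts in all 3 TPEN libraries and 2.34 ± 0.547 CPM in control, at least 47.8-fold lower against a floor of 3 counts over the group. It lies inside the gene DDI2 on the same strand, which makes its count uncertain too.

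The largest rises outside the stress lists came from genes that were almost silent in control. SLC2A9, a urate transporter gene, rose by 7.69 ± 0.31 from 0.0453 to 10.8 CPM, XKR7 by 7.28 ± 0.32, SPOCK2, a matrix proteoglycan gene, by 6.50 ± 0.30, FBXW10B by 5.96 ± 0.29, the receptor gene GPR132 by 5.83 ± 0.45 and ADPRHL1 by 5.76 ± 0.19 (log2, SE, edgeR, n = 3 per group). Control counts were 2, 0 and 1 for SLC2A9, 3, 0 and 1 for XKR7 and 1, 0 and 2 for GPR132. The changes of SLC2A9 and XKR7 were 8.53 and 8.49 without control replicate 1, and that of GPR132 was 6.62 without control replicate 3. SFT2D3 had a fitted change of 6.77 ± 0.56, but its control counts were 3, 0 and 0, so that without control replicate 1 the control group was at 0, and it overlaps WDR33 on the opposite strand. SLC2A9 and FBXW10B also overlap other protein-coding genes, which makes their counts less certain. The antisense RNAs HELZ-AS1 and CDH13-AS2 rose by 6.81 ± 0.24 and 5.74 ± 1.07. Their reads cannot be told from those of HELZ and CDH13 without strand, and without control replicate 3 the changes were 7.46 and 7.20. CDH13-AS2 had 10 counts in TPEN replicate 1 against 133 and 128 in TPEN replicates 2 and 3.

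Ribosomal protein genes rose together by a small amount. Of 72 measured genes 66 rose and none fell, 67 and 0 when adjusted over the list alone, with a median log2 change of 0.47 (camera adjusted p = 2.94e-07, and adjusted p = 0.738 with an estimated correlation). RPL23A rose by 1.52, RPS21, RPLP1 and RPS19 by 0.81 each. Relative to the control mean the median of these genes was 0.28 in TPEN replicate 1, 0.53 in TPEN replicate 2 and 0.56 in TPEN replicate 3 on the log2 scale. Many processed pseudogenes resemble them, so their counts depend on how shared reads were assigned. Ribosome biogenesis genes went both ways, with 15 rises and 8 falls of 28, the same when adjusted over the list alone, including GAR1 (0.98), NOP58 (0.67) and NOP16 (-0.71), and were not called (median 0.23, camera adjusted p = 0.66). Nuclear genes of the respiratory chain had 30 rises and 3 falls of 45, the same when adjusted over the list alone, led by ATP5ME (0.99), NDUFA1 (0.80), UQCRQ (0.75) and COX7A2 (0.70). Their median was 0.28 (camera adjusted p = 0.0320, and adjusted p = 0.757 with an estimated correlation), and the call was lost without control replicate 3, TPEN replicate 2 or TPEN replicate 3 (camera adjusted p = 0.0743, 0.0779 and 0.0706, with a range of 6.78e-05 to 0.757 over its alternatives). Among protein-coding genes classed by transcript length, the shortest class (median 1309 bases) had a median log2 change of 0.13. The longer classes had medians of -0.13 to -0.07. Classed by GC content, medians ran from 0.12 at the lowest to -0.14 at the highest. ATP5ME, NDUFA1, UQCRQ and COX7A2 have lengths of 365, 766, 839 and 914 bases. Whether length or GC content contributed to the rise of the respiratory chain list was not tested.

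Protein-coding genes of the mitochondrial genome went both ways. MT-CO1 fell by 0.46 ± 0.07 and MT-ND4 and MT-CYB by 0.32 each on the log2 scale, while MT-ND3 rose by 0.68. Of 13 protein-coding mitochondrial genes 2 rose and 5 fell, the same when adjusted over the list alone, with a median of -0.03 (camera adjusted p = 0.832), which ran from -0.11 without TPEN replicate 2 to 0.062 without TPEN replicate 1. All mitochondrial transcripts together made up 2.25% ± 0.0729 of counts in control and 2.46% ± 0.159 in TPEN (SD, n = 3, exact two-sided permutation p = 0.2). Within this share the mitochondrial ribosomal RNAs were at 0.456% ± 0.0227 in control and 0.916% ± 0.0319 in TPEN, and the protein-coding part lay between 1.74% and 1.90% in control and between 1.39% and 1.62% in TPEN. Both of these differences had an exact two-sided permutation p of 0.1, the smallest possible here. In the list for mitophagy and mitochondrial dynamics 6 rose and 7 fell of 21, the same when adjusted over the list alone, including BNIP3L (0.82), TFB2M (0.85), NRF1 (-0.85) and PPARGC1B (-1.51). It was not called (median -0.0042, from -0.074 without TPEN replicate 1 to 0.054 without TPEN replicate 2, camera adjusted p = 0.937).

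**Figure D2:**
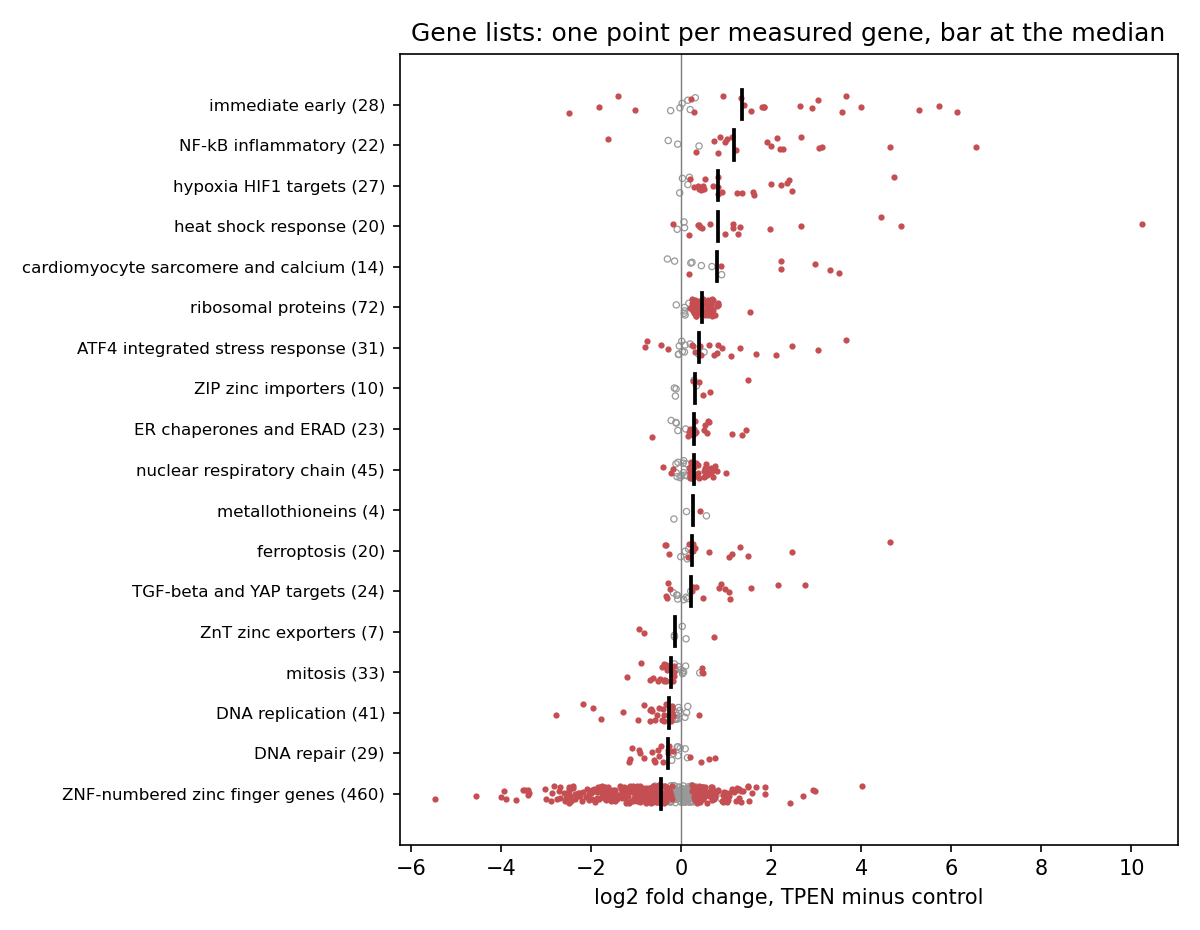
Log2 fold change, TPEN minus control, of each measured gene in the 15 called gene lists and the 3 zinc lists, with red points for an adjusted p below 0.05, open grey points otherwise, black bars at list medians and the number of genes in brackets. The immediate early median stands at 1.36 and the median of the ZNF-numbered genes at -0.45.

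Several cardiac markers rose, from levels that differed widely between genes. ACTC1, cardiac actin, rose from 0.961 ± 0.202 to 10.9 ± 1.61 CPM, a log2 change of 3.51 ± 0.19, and NPPB, the B-type natriuretic peptide gene, from 98.6 ± 9.16 to 459 ± 15.5 CPM (2.22 ± 0.08). LDB3 rose by 2.21 and ANKRD1 by 0.89. The troponin gene TNNT2 had 10 counts over the 3 control libraries and 7 over the TPEN libraries, too few to test. Of 32 sarcomere and calcium genes 14 were measured, 7 rose and none fell, 7 and 0 when adjusted over the list alone, with a median of 0.79 (camera adjusted p = 0.00158, and adjusted p = 0.141 with an estimated correlation). That median ran from 0.47 to 1.00 over the alternatives, and was 0.51 over 28 genes without a low count filter. Cardiac transcription factors changed both ways, with SRF rising by 1.85, MEF2A by 0.91, and GATA6 falling by 1.02. This list had 3 rises and 2 falls of 8, the same when adjusted over the list alone (median 0.08, from 0.021 without TPEN replicate 1 to 0.13 without TPEN replicate 2, camera adjusted p = 0.355). TGF-beta and YAP targets had 12 rises and 4 falls of 24, the same when adjusted over the list alone, with a median of 0.22 (camera adjusted p = 0.00179, and adjusted p = 0.623 with an estimated correlation). Their leading members ID2 (2.74), PMEPA1 (2.15), ID1 (1.55) and SKIL (1.09) are targets and feedback regulators of SMAD signalling.

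Fibroblast and matrix genes were abundant in both groups, as with FN1 at 5482 ± 192 CPM in control, and no measured member changed by more than 0.50 on the log2 scale. Of 28 measured, 3 rose and 8 fell, 2 and 3 when adjusted over the list alone, with LOX at 0.50, THBS1 at 0.49, FN1 at -0.33 and THY1 at -0.29 (median -0.02, from -0.14 without TPEN replicate 1 to 0.034 without TPEN replicate 3, camera adjusted p = 0.927). Of 25 metalloproteinases and inhibitors 8 rose and 5 fell, the same when adjusted over the list alone, and ADAMTS5 and ADAMTS1 fell by 1.00 and 0.77. The median of that list was 0.07, from -0.010 without TPEN replicate 1 to 0.10 without control replicate 2, while its mean was -0.0012 and the test pointed down (camera adjusted p = 0.937). Endothelial markers had 4 rises and 1 fall of 9, the same when adjusted over the list alone, with ESAM at 4.44, VWF at 0.87, FLT1 at 0.57 and KDR at -1.33 (median 0.36, from 0.16 without TPEN replicate 1 to 0.52 without TPEN replicate 2, camera adjusted p = 0.442). The median level of that list was 2.61 CPM in control. ESAM had only 2, 2 and 2 counts in the control libraries, so the size of its rise rested on few counts. Leukocyte markers had 4 rises and no fall of 8, the same when adjusted over the list alone, with CSF1R at 1.49 (median 0.39, camera adjusted p = 0.547), at a median level of 1.33 CPM in control. Epithelial markers had 2 rises and 1 fall of 8, 1 and 1 when adjusted over the list alone, with KRT18 falling by 0.64 (median -0.05, from -0.21 without TPEN replicate 1 to 0.073 without TPEN replicate 2, mean 0.0049, a test pointing down, camera adjusted p = 0.914). Of the adipocyte and skeletal muscle markers 2 of 16 were measured and 0 were called, also when adjusted over the list alone and also at an unadjusted p below 0.05 in edgeR.

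Lipid, proteasome and autophagy genes showed mixed changes. STARD4, a sterol carrier gene, rose by 1.81 and SC5D by 0.61, while MVK and CYP51A1 fell by 0.66 and 0.62, with 6 rises and 10 falls of 24 cholesterol synthesis genes, the same when adjusted over the list alone (median -0.10, from -0.19 without TPEN replicate 1 to -0.053 without TPEN replicate 2, camera adjusted p = 0.914). In fatty acid synthesis SREBF1 fell by 0.85, FASN by 0.67, FADS2 by 0.62 and ACSS2 by 0.55, with 3 rises and 5 falls of 14, the same when adjusted over the list alone (median -0.14, camera adjusted p = 0.467). Proteasome subunits had 11 rises and 5 falls of 31, the same when adjusted over the list alone, with PSMD3 (-0.71), PSMD7 (-0.58) and PSMD11 (-0.53) falling and PSMA6 (0.47) rising (median 0.12, camera adjusted p = 0.735). Of 34 autophagy and lysosome genes 12 rose and 7 fell, 12 and 6 when adjusted over the list alone. MAP1LC3B rose by 1.04, GABARAPL1 by 0.83 and ATG5 by 0.72, and TFEB, a transcription factor of lysosomal genes, had a change of -1.38 (median 0.03, from 0.0033 without TPEN replicate 1 to 0.063 without TPEN replicate 3, camera adjusted p = 0.67).

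Further called members of these lists lost their call under an alternative. They were EDA2R (0.89) of the p53 targets, XAF1 (-1.09) of the interferon list, HAND2 (-0.88) of the cardiac factors, ADAM8 (0.73) and MMP11 (-0.66) of the metalloproteinases, LAPTM5 (0.79) and LCP1 (0.70) of the leukocyte markers, OCLN (0.31) of the epithelial markers, and the histone genes H2BC21 (-0.82), H2AC18 (0.78), H2BC11 (-0.61) and H2BC12 (-0.34). DESeq2 did not call SLC30A3 or any of these except XAF1, OCLN and H2BC12. In edgeR, calls were lost without control replicate 1 for ADAM8 (0.62), H2BC11 (-0.57), H2BC12 (-0.24), H2BC21 (-0.73), LCP1 (0.53) and OCLN (0.25), without control replicate 2 for HAND2 (-0.68), LAPTM5 (0.73) and XAF1 (-0.97), and without control replicate 3 for ADAM8 (0.55), H2BC11 (-0.55) and LAPTM5 (0.68). They were lost without TPEN replicate 1 for ADAM8 (0.47) and H2BC11 (-0.51), without TPEN replicate 2 for ADAM8 (0.77), H2BC12 (-0.29), H2BC21 (-0.71) and LAPTM5 (0.67), and without TPEN replicate 3 for H2BC11 (-0.59).

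Terms attached to genes in the deposited table gave a parallel view. Genes that rose at least 2-fold were enriched for 15 GO terms, including hormone activity (13 of 27 genes, Fisher's exact adjusted p = 0.000274), cytokine activity (21 of 72, adjusted p = 0.00102) and inflammatory response (34 of 162, adjusted p = 0.00387). They were also enriched for 27 KEGG pathways, among them neuroactive ligand-receptor interaction (33 of 110, Fisher's exact adjusted p = 2.04e-10), TNF signaling (18 of 84, adjusted p = 0.00188) and NF-kappa B signaling (15 of 61, adjusted p = 0.0018). With all tested genes as the background, only 1 KEGG pathway was called for rising genes. Genes that fell at least 2-fold were enriched for 16 GO terms, most of them on transcription, such as negative regulation of DNA-templated transcription (75 of 361, Fisher's exact adjusted p = 3.36e-13) and sequence-specific DNA binding (44 of 234, adjusted p = 9.09e-06). The KEGG calls among falling genes were Wnt signaling (22 of 114, Fisher's exact adjusted p = 0.000532) and the herpes simplex virus 1 infection pathway (95 of 396, adjusted p = 2.17e-28). In the latter 79 of the 95 falling genes were ZNF-numbered zinc finger genes, as were 269 of the 396 tested genes of that pathway.

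In total 15 of 41 lists were called with the preset correlation of 0.01, 11 up and 4 down, and 1 with an estimated correlation. The estimate reached 0.80 for the ribosomal proteins. For the endoplasmic reticulum, ferroptosis and sarcomere lists it was -0.0098, -0.019 and -0.020, below the preset value. The loss of those calls therefore does not show that their genes are correlated. For the DNA replication list the estimate was 0.018, near the preset value. Its unadjusted camera p nevertheless went from 3.63e-06 to 0.0141 with an estimated correlation. The estimated setting thus weakened calls by more than the correlation alone. The test with the preset correlation called up to 16 lists when the libraries were regrouped so that each group mixed control and TPEN. Such groups hold control and TPEN libraries in unequal numbers. Part of the treatment difference therefore stays, and these regroupings do not show what chance gives. The reference genes GAPDH (log2 change -0.03 ± 0.07) and ACTB (0.0098 ± 0.0811) did not pass the test (edgeR adjusted p = 0.769 and 0.925), and the sign of each turned with the scaling, GAPDH to 0.0093 with upper-quartile scaling and ACTB to -0.011 with library size alone. Besides the genes already marked, these named genes overlap another annotated protein-coding gene on the same or the opposite strand, so that their counts are less certain: SLC39A1, SLC39A3, SLC39A7, SLC39A9, SLC30A3, SCO2, ATP7A, SLC31A2, COX17, DNAJB9, SYVN1, DNAJB1, OSGIN1, GPX8, PRDX1, FAS, CASP9, ANKRD37, ENO2, CCNE2, PLK1, BUB1B, RAD54L, MVK, CYP51A1, SREBF1, FADS2, ACSS2, MT-ND4, ATP5ME, NDUFA1, UQCRQ, BNIP3L, MAP1LC3B, ATG5, PSMA6, RPL23A, NOP16, IRF9, FOSB, MEF2A, LOX, THBS1, KRT18, MMP11 and ZNF619.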

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

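All tests here were planned except the restrictions to protein-coding genes and to genes with 2 or more exons, which were chosen only after the result was seen. Over the other scalings, filters, tools and libraries left out, the number of genes changed ran from 8695 to 11257, and 8389 to 9743 of the 9806 called genes were called again with the same sign and 0 with the opposite sign. With the replicate block, 10149 genes changed, 3065 of them at least 2-fold, and 15 lists were called. Deviations from the group mean, over 9399 genes, correlated at 0.0987, -0.24 and 0.34 between same-numbered libraries. Between libraries of different number they correlated at -0.38 to 0.30. The same-numbered values went both ways, so pairing was not shown. Deviations within a group are tied to each other, and genes are not independent replicates. Among named genes, 2525 values under an alternative kept their sign and side of the threshold, 37 lost the call, 12 gained it and 13 reversed. For lists these were 549, 19, 20 and 12, and DESeq2 offers no set test.

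Without the low count filter 2999 genes were at least 2-fold higher, with 35089 genes tested. With protein-coding genes only, 1932 changed at least 2-fold and 1057 were higher, against 1938 and 987 of the protein-coding genes when all genes were fitted. With 2 or more exons only, 8736 changed and 2338 at least 2-fold. Camera with an estimated correlation called 1 of the lists and fry 28. Without a fold minimum 26 GO terms were called for higher genes, 47 for lower genes and 4 KEGG terms for lower genes. With all tested genes as background 9 GO terms and 1 KEGG term were called for higher genes. There the higher genes were 1864 of 16010, a larger share than the 387 of 5283 genes with a KEGG term. More of them were thus expected in each KEGG term. For lower genes 2 KEGG terms were called with either background. The cause of the other differences was not tested.

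The reversed values all belonged to genes or lists that were not called. GAPDH was 0.0093 with upper-quartile scaling, ACTB -0.011 with library size only, -0.039 without a low count filter and -0.0085 with DESeq2, and SLC30A5 -0.028 without a filter. With a filter of 1 CPM in 3 libraries the medians were 0.020 for mitophagy and mitochondrial dynamics, -0.013 for interferon response and 0.098 for metalloproteinases, and with limma voom -0.035 for interferon response and 0.068 for metalloproteinases. For these 2 lists it was the direction of the set test that turned. Medians of lists not called also changed sign with upper-quartile scaling for mitochondrial DNA genes (0.0090), mitophagy (0.032) and fibroblast and matrix (0.021), without a filter for pyroptosis and necroptosis (0.028) and autophagy (-0.020), and with 1 CPM in 3 libraries for cardiac transcription factors (-0.0068) and fibroblast and matrix (0.0089). With RLE scaling that of mitophagy was 0.000995. Leaving out each library gave -0.069 to 0.27 for MT1E, -0.024 to 0.062 for SLC30A5, -0.088 to 0.015 for GAPDH and -0.091 to 0.054 for ACTB. The list medians ran from -0.18 to -0.068 for ZnT zinc exporters, -0.11 to 0.062 for mitochondrial DNA genes, -0.074 to 0.054 for mitophagy, -0.096 to 0.023 for interferon response, -0.14 to 0.034 for fibroblast and matrix, -0.014 to 0.15 for iron handling, -0.21 to 0.073 for epithelial markers and -0.010 to 0.10 for metalloproteinases. The cause was not tested.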

Other observations

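The patterns below were noticed in these data and tested on the same data, and the tests against low counts, genomic DNA in the TPEN libraries and transcript length bias were chosen only after the result was seen, as were the readings of the single-exon tests of overlap and of low counts by their intervals. The permutation tests (5 in the family, 100000 resamples) treat genes as independent, which they are not.

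Among protein-coding genes, the 278 whose representative transcript has a single exon had a median log2 change of -0.24, with 120 falling and 71 rising. Of them 43% fell, against 39%, 30%, 29% and 37% of genes with 2, 3 to 4, 5 to 9 and 10 or more exons. Falls of at least 2-fold made up 25%, against 18%, 10%, 7% and 5%. Genes with 10 or more exons also leaned down, with a median of -0.11. Whether single-exon genes fell more often than others was not tested. With GC content, length and expression in the model the single-exon coefficient was -0.38 ± 0.05 (SE), which argues against these biases as the whole cause, and olfactory receptor genes held 0.61 times as many counts per 1000000 in control as in TPEN, which argues against genomic DNA in the control libraries. The 141 single-exon genes that overlap no annotated gene had a median of -0.27 (95% interval -0.50 to -0.12, 64 fell and 29 rose), which argues against shared reads as the whole cause, although it missed the planned bound of 0.3, a bound deeper than the pattern itself. Multi-exon genes matched on CPM gave a gap of -0.21 (95% interval -0.35 to -0.045, two-sided permutation p = 0.0018, adjusted 0.003), and with the model above, which holds CPM, this argues against low counts as the whole cause, although it missed the bound of 0.3, also deeper than the pattern, and a part stays open. No biological explanation was tested.

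Weakly expressed genes (mean below 2 CPM) lying within 10 kb downstream of an expressed gene on the same strand had a median log2 change of 0.76, with 98 rising and 13 falling of 188, against 0.37 in 69 genes that lie head to head with one (gap 0.38, two-sided permutation p = 0.038, adjusted 0.0475). Transcription running past the end of the upstream gene may contribute, and the strand of the reads needed to show it is not in these data. Genomic DNA in the TPEN libraries was first tested on 405 olfactory receptor genes, whose log2 change of 0.71 lay between the bounds set for that test and decided nothing, so a matched comparison was chosen in its place after that value was seen. In it, weak genes of like CPM without an expressed neighbour had a median of 0.19, a gap of 0.56 (permutation p = 3e-04, adjusted 0.00075), which argues against genomic DNA as the whole cause, although the olfactory rise leaves a part open. Among genes that overlap no annotated gene the gap was 0.59 (73 against 25 genes, lower end of the 95% interval -0.15, permutation p = 0.0855), so shared reads cannot be told apart because the genes are too few.

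Ribosomal protein genes rose together, with a median of 0.47. Genes matched on transcript length and CPM had a median of 0.16, a gap of 0.31 (two-sided permutation p = 1e-05, the smallest these permutations can give, adjusted 5e-05), which argues against transcript length bias as the whole cause. Leaving out a TPEN library gave medians of 0.42 to 0.55, which argues against a single library. Reads shared with processed pseudogenes and a change in RNA quality were not tested, so both stay open beside a response to TPEN.

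The 6 libraries can be split in 10 ways, so the share of splits with a result as large is never under 0.1. The real split gave 9806 changed genes against a highest other of 0, and 3030 changed at least 2-fold against 0, with 1 split as large in each case. It gave 15 called lists against a highest other of 16, with 3 splits as large. Each of the other splits mixes control and TPEN libraries in both groups, which keeps part of the treatment difference and widens the spread within groups. Counts of 0 changed genes were therefore likely beforehand. These splits do not show how many genes or lists chance would call.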
